A study of Mus musculus with 11 samples.

How the data were processed

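The series measured mRNA in primary mouse granulosa cells, the somatic cells of the ovarian follicle that surround the oocyte and make steroid hormones. Per the labels, cells of RjOrl:SWISS mice received 30 pmol of siRNA by lipofection, the mix was removed at 5 h, and RNA was taken at 30 h. There were 11 libraries: 3 from cells given a nontargeting scrambled siRNA (called scramble) and 2 from each of 4 pools of siRNAs against Akt1. Each pool held 3 of 4 Akt1 siRNAs. Pool 1 lacked siRNA 9, pool 2 lacked siRNA 7, pool 3 lacked siRNA 8 and pool 4 lacked siRNA 6. The protocol and the sample titles number the pools under different names, and matching them by number is an assumption made here. The siRNA sequences are not given in the sources used here.

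Per the labels, libraries were made from 1.3 µg of total RNA with a stranded mRNA kit and read as single 75-base reads. ERCC spike-in sequences are among those counted in the deposited files. The submitters' processing notes name bcl2fastq 2.15.0, FastQC 0.11.5, cutadapt 1.9.1, TopHat2, featureCounts 1.5.0-p2, DESeq2 and the mouse build mm10. The order of these steps, their settings and the strand setting of the counting are not given in the sources used here. The deposited count files hold whole-number counts of reads per gene symbol, not normalized by the authors, with 24490 genes and 92 ERCC sequences in 24582 lines. The ERCC lines were kept out of library sizes and tests and took 0.268% to 0.788% of the counts of a library. The authors' deposited table of all pools against scramble holds, per its column names, a mean signal (normalized counts averaged over libraries), log2 fold changes with their standard errors, a Wald score, and p-values with adjusted p-values. Its design, its software version and any shrinkage of the fold changes are not given in the sources used here. Reads shared by paralogs, or by genes that overlap, cannot be separated from the deposited counts.

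Depth was 23851293 to 32643158 reads in genes per library. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (14144 genes kept) and the quasi-likelihood F test, which is two-sided. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, with no minimum fold. The comparison of all pools with scramble used 2 groups, 8 libraries against 3, because the authors' deposited table is named for that comparison. Differences between pools then count as error. The 8 libraries are still treated as independent, although they come as 2 from each of 4 pools. Standard errors and p-values of that comparison may therefore be too small. Each pool against scramble, the test of any difference among the 4 pools (3 degrees of freedom) and each pool against the mean of the other 3 pools used 1 fit with 5 groups, which share 1 estimate of spread. The groups, the tests of these comparisons, the gene lists and the alternatives listed with them were fixed before the data were examined. Tests and alternatives added later are named as such where their results are given. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

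Named genes followed a fixed rule. Akt1 and Akt2 were always named. The rule then took the 8 largest increases and 8 largest decreases among called genes with an average log2 CPM of at least 2 and each of the 4 pools on the same side of scramble, and up to 2 called members of each list by size of change. Between pools it took the 8 smallest p-values of the 4-pool test and up to 3 per pool against the others. Predicted genes, pseudogenes and mitochondrial genes were passed over. With all libraries the rule left Akt1 alone in the comparison of all pools, so it was applied again to the fit without scramble replicate 1. That repeat, and the naming of list members that passed only with adjustment over the list alone, were chosen after the values were seen. Some genes that the rule takes are not reported here. Uncalled list members given as examples are those with the highest average log2 CPM.

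Gene lists for granulosa cell function, lipid and steroid synthesis, signalling, stress, growth, metabolism and other ovarian cell types were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 3 and a preset correlation of 0.01 between genes. There were 28 lists, of which 27 had the 5 members needed for a test. Beside camera stand camera with an estimated correlation and fry, which tests whether a list's genes move on balance in one direction and compares them with no other genes. Lists were also tested in each pool against scramble, which was chosen after the values were seen. List medians and means are over edgeR log2 fold changes unless given as log2 CPM differences or for single pools, which are over log2 CPM. Alternatives were another scaling (RLE), no low-count filter, CPM above 1 in all libraries, DESeq2 1.42.0, limma-voom with and without the group (a pool or scramble) as a random effect, a minimum fold of 1.5, the replicate number as a block, each pool fitted with scramble alone, and the omission of each library or pool.

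Gene positions, transcript lengths and 3′ UTRs came from GENCODE M21 on GRCm38, the assembly also called mm10. A transcript length was found for 13761 tested genes (97.3%) and an annotated 3′ UTR for 13073 (92.4%). All 16384 words of 7 bases were searched in the 3′ UTRs of 12966 genes, in the 200 genes most changed in each direction in each pool against the others, against other genes of like 3′ UTR length. Unchanged pools were simulated 50 times against the scramble libraries. They were centred on the mean of those libraries, so a chance shift of that mean is not part of the simulation. Components and correlations used log2 CPM with a prior count of 2. Lists were also compared with 10000 random lists of the same size matched on mean expression, or 2000 for single pools against single scramble libraries.

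The procedures were tested on simulated data with known changes. In the comparison of all pools with scramble, run on 14044 genes, the test called 19.4% of 67 genes changed by 0.5 log2, 91.0% of 67 changed by 1 and 100% of 66 changed by 2, with 9 false calls. In pool 2 against the other pools, on 14030 genes, it called 14.9%, 80.6% and 100%, with 8 false calls. Apart from the set changes, all simulated libraries shared 1 mean per gene. No scramble library stood apart and pools did not otherwise differ, unlike in the real data, so these rates may not hold there. A list shifted by −0.4 log2 was recovered (camera adjusted p = 1.95e-20) with 0 of the other lists called. Simulated genes were drawn independently, while in the real data the estimated correlation within a list reached 0.86, for ribosomal proteins. The simulation therefore does not measure false list calls in the real data. In the word search, 20 of 20 planted words ranked first, and 1 of 20 random gene sets gave a word past the threshold.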

Results

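RNA-seq gave 11 libraries of primary mouse granulosa cells, 3 from cells given a nontargeting scrambled siRNA and 8 from cells given siRNA pools against Akt1, a serine/threonine kinase that acts downstream of PI3K. The 8 Akt1 libraries came from 4 pools of 3 siRNAs, with 2 libraries per pool. Depth was 23851293 reads in genes in scramble replicate 3, the shallowest library, and 32643158 in scramble replicate 1, the deepest. The 4 pools each left out another of 4 Akt1 siRNAs, so the design asks what Akt1 knockdown changes in these cells and what depends on a single siRNA.

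Scramble replicate 1 stood apart from the other 10 libraries. Its median correlation with them across genes was 0.948, against at least 0.989 for every other library. It lay at −93.9 on component 1, which held 55.6% of the variance of log2 CPM, and was the library farthest from the median for 9512 of 14144 genes (67.3%). Short transcripts were higher in it and long ones lower. Against the other scramble libraries, the median was 0.84 log2 for genes in the shortest of 5 transcript length classes (median length 1256 bases) and −0.94 for the longest (6712 bases). Component 2 (23.1%) held scramble replicates 2 and 3 together with both pool 2 libraries at −22.2 to −25.3, pools 1 and 4 at 7.50 to 10.5, and pool 3 at 25.9 and 28.0. No libraries of a group agreed within sampling noise, since the chi-square per degree of freedom of every same-group pair was at least 2.72.

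**Figure D1:**
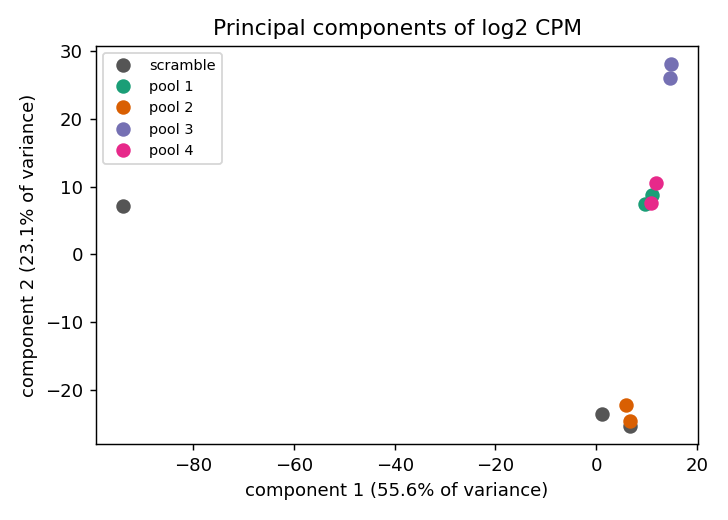
Principal components of log2 CPM over 14144 genes; each point is 1 library, coloured by group, with the percent of variance on each axis. Scramble replicate 1 lies alone at −93.9 on component 1, and component 2 places the pool 2 libraries (−22.2 and −24.5) beside scramble replicates 2 and 3 (−23.4 and −25.3).

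Akt1, the target of the siRNAs, fell in every pool. It was counted at 530, 441 and 412 CPM in the scramble libraries and at 53.8 to 79.6 CPM in the 8 pool libraries. Mean levels were 60.3 ± 3.74 CPM in pool 1, 55.0 ± 1.80 in pool 2, 78.5 ± 1.64 in pool 3 and 58.1 ± 4.91 in pool 4 (SD, n = 2 each), against 461 ± 61.6 in scramble (SD, n = 3). The pools thus kept 13.1%, 11.9%, 17.0% and 12.6% of the scramble level. Over all pools the log2 fold change was −2.87 ± 0.13 (SE), a 7.32-fold fall (edgeR adjusted p = 4.2e-07, lower in 8 of 8 libraries). Against scramble the 4 pools had log2 fold changes of −2.93, −3.07, −2.55 and −2.99, each with SE 0.14 and edgeR adjusted p at or below 0.000221. Akt1 (ENSMUSG00000001729.14) lies on the minus strand of chromosome 12 at 112653821 to 112674884 in mm10.

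Akt2, which encodes a related kinase, did not pass the test with all libraries. It was at 54.8 ± 1.23 CPM in the pools (SD, n = 8) and 58.2 ± 4.48 in scramble (SD, n = 3; log2 −0.09 ± 0.07 SE, edgeR adjusted p = 0.376). Akt1 differed between pools by less than the test could call (3-degree F test, edgeR adjusted p = 0.239), with pool 3 above the mean of the other pools by 0.44 log2 (edgeR adjusted p = 0.0873). That difference passed without scramble replicate 1, as did a lower level in pool 2 (edgeR adjusted p = 0.000427).

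**Figure D2:**
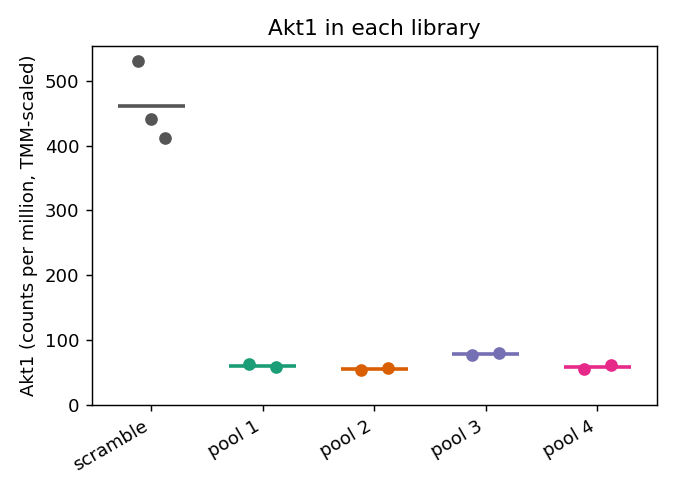
Akt1 CPM, TMM-scaled; points are libraries and horizontal lines are group means, from 0. The 3 scramble libraries lie between 412 and 530 CPM and the 8 pool libraries between 53.8 and 79.6.

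The comparison of all pools with scramble asked which genes changed with Akt1 knockdown whatever the pool. With all 11 libraries, Akt1 was the single gene of 14144 past the threshold in edgeR, while 4041 genes had an unadjusted p below 0.05. DESeq2 called 1147 genes, limma-voom called 1, and the mean of the pools in the 5-group fit gave 901. The count was 66 without scramble replicate 1, 2 without scramble replicate 2, 2336 without scramble replicate 3, 41 without pool 2 replicate 2 and 2 without pool 3 replicate 1. Leaving out both pool 2 libraries gave 1390.

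Without scramble replicate 1, 16 genes rose and 50 fell. Among those that rose were Pik3ip1, which encodes an inhibitor of PI3K, by 0.69 ± 0.11 log2 (SE; 8 pool libraries against 2), the sorting nexin Snx30 by 0.52 ± 0.09, the transcription cofactor Lbh by 0.44 ± 0.07, Stard13 by 0.38 ± 0.04 and the receptor adaptor Gab1 by 0.35 ± 0.05. Mlf1 (0.61 ± 0.10), Col4a3 (0.36 ± 0.07) and Bcl7a (0.35 ± 0.06) completed the 8 largest increases. After Akt1, those that fell most were the retinoic acid binding protein gene Crabp2 by 0.91 ± 0.10 log2, the calcium pump gene Atp2a2 by 0.83 ± 0.16, the actin-severing protein gene Scin by 0.83 ± 0.15 and the microtubule-associated protein gene Map1a by 0.76 ± 0.06. Pm20d2 fell by 0.71 ± 0.13, the enolase gene Eno3 by 0.70 ± 0.08 and the lipoprotein receptor gene Lrp8 by 0.64 ± 0.11. Over these 15 genes the edgeR adjusted p ran from 0.000592 for Map1a to 0.0491 for Atp2a2. With all libraries none of these 15 genes passed, and their edgeR adjusted p ran from 0.0503 (Crabp2, log2 −1.29 ± 0.17) to 0.545 (Mlf1, log2 0.17). Mlf1 was at −0.01 without scramble replicate 2.

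Gene lists were tested in the same comparison, where edgeR called 1 gene with all libraries and 66 genes without scramble replicate 1. With all libraries camera called 13 of 27 lists, 12 of them lower in the pools, and without scramble replicate 1 it called 12, of which 11 were lower. With an estimated correlation camera called 0 lists in either case, with the smallest adjusted p at 0.322 and 0.107, while fry called 6 lists with all libraries. Without scramble replicate 1 the smallest fry adjusted p was 0.0016, for the unfolded protein response, luteal, glycolysis and Sertoli lists. Cholesterol synthesis (0.0635) and interferon-stimulated genes (0.522) were among the lists that fry did not pass there. Several lists share genes, such as Hsd17b7 in the steroid and cholesterol lists, so their results are not independent.

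Genes of steroid hormone synthesis were lower in the pools. The median log2 fold change of the 18 members was −0.40, and 9 members were lower and 0 higher adjusted over the list alone, while edgeR called 0 over all genes (camera adjusted p = 0.00137, adjusted p = 0.37 with an estimated correlation). The median of 17 members was −0.26 without scramble replicate 1. Then 2 members fell over all genes, Fdx1, which passes electrons to mitochondrial steroid hydroxylases (−0.40 ± 0.05 SE, edgeR adjusted p = 0.0247), and the lipoprotein receptor gene Scarb1 (−0.33 ± 0.06, edgeR adjusted p = 0.0491). Adjusted over the list alone 11 were lower, among them the aromatase gene Cyp19a1, the side-chain cleavage gene Cyp11a1 (−0.26 ± 0.05) and the nuclear receptor genes Nr5a1 and Nr5a2 (camera adjusted p = 0.000224, adjusted p = 0.144 with an estimated correlation). The list's median was 0.29 higher in scramble replicate 1 than in the other scramble libraries.

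Cholesterol synthesis genes were also lower over all pools, and fatty acid synthesis genes were lower without scramble replicate 1. The 24 cholesterol genes had a median of −0.19, with 0 called by edgeR over all genes and 6 lower adjusted over the list alone (camera adjusted p = 0.00591, adjusted p = 0.575 with an estimated correlation); the camera adjusted p was 0.095 without scramble replicate 2, at a median log2 CPM difference of −0.10 against −0.18 with all libraries, and 0.146 without both pool 2 libraries (−0.13). In single pools with all libraries the list passed in pool 2 (median log2 CPM difference −0.38, camera adjusted p = 3.72e-10, adjusted p = 0.175 with an estimated correlation) and not in pools 1, 3 and 4 (0.222, 0.365 and 0.0886). It passed without scramble replicate 1 in pools 1, 2 and 4 (0.0391, 6.63e-23 and 0.00923, adjusted p = 0.668, 0.157 and 0.682 with an estimated correlation) and not in pool 3 (0.194, median −0.09). The median without scramble replicate 1 was −0.20, with 3 members lower over all genes and 9 adjusted over the list alone (camera adjusted p = 2.17e-06, adjusted p = 0.408 with an estimated correlation). These included Mvd, an enzyme of the mevalonate pathway (−0.47 ± 0.09 SE, edgeR adjusted p = 0.0466). The 14 fatty acid synthesis genes were called without scramble replicate 1, with a median of −0.25 and 10 members lower adjusted over the list alone, among them Fasn, Acaca, Scd1 and Scd2, and 0 over all genes (camera adjusted p = 2.17e-06, adjusted p = 0.107 with an estimated correlation). With all libraries the median was −0.12, 0 members passed either way, and the camera adjusted p was 0.171. This list's median was 0.61 log2 lower in scramble replicate 1 than in the other scramble libraries.

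Genes of the unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, were lower too. The median of 20 members was −0.35 with all libraries, with 13 lower and 1 higher adjusted over the list alone and 0 called over all genes (camera adjusted p = 0.000713, adjusted p = 0.322 with an estimated correlation). It was −0.18 without scramble replicate 1, with 15 lower adjusted over the list alone and 1 over all genes, the transcription factor gene Xbp1 (−0.26 ± 0.05 SE, edgeR adjusted p = 0.0461; camera adjusted p = 1.25e-06, adjusted p = 0.107 with an estimated correlation). The chaperone genes Hsp90b1 (−0.19 ± 0.05) and Hspa5 (−0.14 ± 0.04) were among the 15. The ATF4 and amino acid response list had a median of −0.36 (camera adjusted p = 0.000631, adjusted p = 0.575 with an estimated correlation), with 10 of 26 lower adjusted over the list alone. Its median was −0.10 without scramble replicate 1 (camera adjusted p = 0.00191, adjusted p = 0.402 with an estimated correlation), with 2 lower adjusted over the list alone and 1 over all genes. That gene was the mTORC1 inhibitor gene Ddit4 (−0.37 ± 0.07 SE, edgeR adjusted p = 0.0466), which is also on the FOXO list. Glycolysis and hypoxia genes had medians of −0.19 with all libraries (camera adjusted p = 0.000935, adjusted p = 0.555 with an estimated correlation) and −0.10 without scramble replicate 1 (0.00941, adjusted p = 0.107 with an estimated correlation), with 9 and 1 of 28 lower adjusted over the list alone.

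Several lists of ovarian cell type markers were lower as well. Granulosa cell markers had a median of −0.29 over 19 members, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0148, adjusted p = 0.575 with an estimated correlation), and the call was lost without scramble replicate 2 (0.085) or 3 (0.10), where the median log2 CPM difference was −0.29 and −0.31 against −0.23 with all libraries. The median was −0.41 without scramble replicate 1, and the inhibin subunit gene Inhba was the 1 member lower adjusted over the list alone (camera adjusted p = 0.00108, adjusted p = 0.499 with an estimated correlation). Pool 2 stood apart in this list: against scramble replicates 2 and 3 its median was −0.05, against −0.37, −0.53 and −0.43 in pools 1, 3 and 4, and its camera adjusted p against scramble was 0.613 (0.176 without scramble replicate 1). Luteal and ovulatory genes had a median of 0.02, a mean of −0.04 and a camera direction of lower (camera adjusted p = 0.816, 4 of 19 lower adjusted over the list alone). Their median was −0.22 without scramble replicate 1, with 7 lower adjusted over the list alone, Ptgs2, Ereg and Btc among them (camera adjusted p = 0.00101, adjusted p = 0.107 with an estimated correlation). Sertoli and testis genes had medians of −0.29 (camera adjusted p = 0.0148, adjusted p = 0.322 with an estimated correlation) and −0.17 (0.0493, adjusted p = 0.19 with an estimated correlation) with 2 and 3 of 12 lower adjusted over the list alone. In single pools that list passed in pool 2 alone, with all libraries (0.00586, adjusted p = 0.245 with an estimated correlation) and without scramble replicate 1 (0.0245, adjusted p = 0.157 with an estimated correlation). Fgf9, a growth factor gene on that list, fell by 0.52 ± 0.08 SE without scramble replicate 1 (edgeR adjusted p = 0.041). Theca and stroma markers had medians of −0.23 (camera adjusted p = 0.0986, 3 of 18 lower adjusted over the list alone) and −0.17 (0.00808, adjusted p = 0.488 with an estimated correlation, 0 adjusted over the list alone). In pool 2 the theca and stroma median was 0.01 against scramble replicates 2 and 3 (camera adjusted p = 0.637 against scramble, 0.203 without scramble replicate 1).

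Interferon-stimulated genes were the 1 list called higher over all pools with all libraries. The median of 31 members was 0.53, and 0.36 without scramble replicate 1, with 0 members past the threshold over all genes or adjusted over the list alone in edgeR. Camera adjusted p was 0.000946 and 0.00937 (adjusted p = 0.575 and 0.722 with an estimated correlation). In single pools the list passed in pools 1 and 4 (camera adjusted p = 8.48e-11 and 0.000338, adjusted p = 0.413 and 0.575 with an estimated correlation) and not in pools 2 and 3 (0.452 and 0.218). Medians against scramble replicates 2 and 3 were 0.66 and 0.43 in pools 1 and 4, and 0.02 and 0.16 in pools 2 and 3. Members below 0 numbered 4 of 31, and Bst2, the member with the highest average log2 CPM, was 1 of these at −0.54 ± 0.19 log2 (SE) and did not pass.

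Other calls stood with scramble replicate 1 and were lost without it. Oxidative phosphorylation genes had a median of −0.47 with 19 of 28 lower adjusted over the list alone (camera adjusted p = 2.4e-05, adjusted p = 0.575 with an estimated correlation), and −0.04 without that library (camera adjusted p = 0.169). Cytosolic ribosomal protein genes went from −0.49 (0.000209, adjusted p = 0.575 with an estimated correlation) to 0.02 (camera adjusted p = 0.292), with 0 of 30 past the threshold adjusted over the list alone. In scramble replicate 1 these 2 lists were 1.05 and 1.15 log2 above the other scramble libraries. The lysosome list (−0.19, 0.00693, 7 lower and 1 higher adjusted over the list alone) and the surface epithelium markers (−0.37, 0.0203, 0 adjusted over the list alone) had a camera adjusted p of 0.595 without it, at medians of 0.01 and −0.17. The cytoskeleton list (−0.20, 0.0325, 13 lower and 5 higher adjusted over the list alone) lost its call without that library (0.365) at a median of −0.24, no smaller in size than with it, and had 0.0602 to 0.0653 without scramble replicate 2 or either pool 1 library. With an estimated correlation the adjusted p of each of these 3 lists was 0.575. The cytoskeleton list passed without scramble replicate 1 in opposite directions in single pools, lower in pool 1 (median −0.38, 0.000404) and higher in pool 2 (0.07, 0.000483), with adjusted p = 0.508 and 0.478 with an estimated correlation. The lysosomal protease gene Ctsl fell by 0.45 ± 0.08 SE without scramble replicate 1 (edgeR adjusted p = 0.0466). Extracellular matrix genes had a median of 0.06 with all libraries (camera adjusted p = 0.523) and −0.12 without scramble replicate 1, with 10 lower and 1 higher of 34 adjusted over the list alone (0.00108, adjusted p = 0.402 with an estimated correlation). The 10 included the collagen genes Col1a1, Col3a1 and Col6a1.

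Over all pools camera called 0 of the other 10 lists with at least 5 members in either setting, with adjusted p from 0.0671 to 0.977 with all libraries. With all libraries and without scramble replicate 1, medians were 0.13 and −0.05 for the AKT and PI3K pathway and 0.24 and 0.06 for FOXO-induced genes, to which Pik3ip1 and Ddit4 belong. They were 0.10 and 0.09 for mitosis, −0.07 and 0.01 for S phase, 0.08 and 0.05 for p53 targets, and 0.07 and 0.06 for apoptosis regulators, which fry called higher (adjusted p = 0.0108) and camera did not (0.288, adjusted p = 0.575 with an estimated correlation). NF-kB genes had −0.01 and −0.04, TGF-beta and BMP response genes −0.01 and −0.12, endothelial markers 0.16 and 0.05, and immune cell markers 0.40 and 0.97. Oocyte markers had 3 measured members and a median of −0.23. In single pools, mitosis genes passed as higher in pool 3 (median log2 CPM difference 0.27, camera adjusted p = 0.00111, adjusted p = 0.136 with an estimated correlation). They passed without scramble replicate 1 as higher in pool 3 (3.51e-05, adjusted p = 0.503 with an estimated correlation) and lower in pool 2 (0.00169, adjusted p = 0.478 with an estimated correlation), so their medians over all pools join opposite directions. In pool 2, S phase genes were called lower (0.0070, adjusted p = 0.551 with an estimated correlation), and the AKT list (0.0346, adjusted p = 0.674 with an estimated correlation) and TGF-beta genes (0.0482, adjusted p = 0.245 with an estimated correlation) higher; without scramble replicate 1 the AKT list did not pass (0.171), while S phase (0.0107) and TGF-beta genes (0.0278) did (adjusted p = 0.489 and 0.455 with an estimated correlation). Adjusted over the list alone, 1 member was higher and 1 lower in the AKT and NF-kB lists, 2 and 2 in the FOXO list, 2 and 3 among apoptosis regulators and 1 and 3 in the TGF-beta list, with 1 higher among p53 targets, 2 lower in S phase, 1 lower among immune markers and 0 in the mitosis and endothelial lists. Median, mean and camera direction differed in sign for luteal genes, NF-kB genes and p53 targets with all libraries, and for NF-kB, S phase and lysosome genes without scramble replicate 1.

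**Figure D3:**
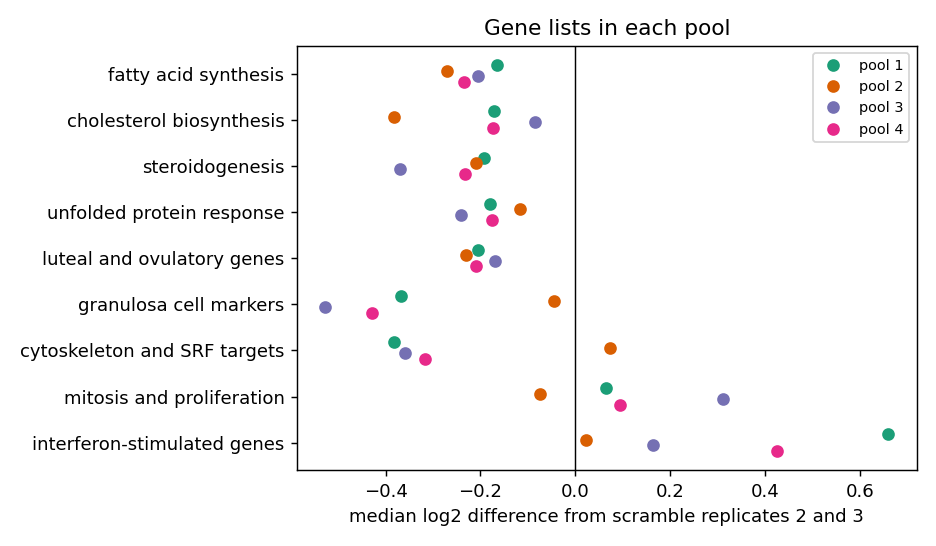
Median log2 difference of 9 gene lists in each pool from scramble replicates 2 and 3; each point is 1 pool and the vertical line is 0. Steroidogenesis lies at −0.19 to −0.37 in the 4 pools, while interferon-stimulated genes lie at 0.66 in pool 1 and 0.02 in pool 2.

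The 4 pools against scramble asked whether each set of siRNAs gave the same changes. Akt1 was the 1 gene called in pool 2, where 653 genes had an unadjusted p below 0.05 in edgeR and DESeq2 called 28. In pool 1, 65 genes rose and 208 fell, in pool 4, 82 rose and 281 fell, and in pool 3, 613 rose and 967 fell. Fitted with the scramble libraries alone, which leaves fewer samples, no pool gave a called gene in edgeR, not even Akt1. Without scramble replicate 1 the counts were 4044 in pool 1, 618 in pool 2, 6864 in pool 3 and 4364 in pool 4, and DESeq2 on all libraries called 788 in pool 1 and 872 in pool 4. Without each other library in turn they were 9 to 219 in pool 1, 210 to 1746 in pool 3 and 17 to 327 in pool 4, lowest without a library of the pool itself.

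Gene lists were also tested in each pool against scramble, a comparison added after the values were seen. Of 108 such tests camera called 45 with all libraries and 41 without scramble replicate 1, and 0 with an estimated correlation (smallest adjusted p = 0.0807 and 0.157). Steroidogenesis and the unfolded protein response were called lower in all 4 pools in both settings, and granulosa markers in pools 1, 3 and 4. Fatty acid synthesis was called lower in pool 2 with all libraries and in all 4 pools without scramble replicate 1. The ATF4 and glycolysis lists were called lower in all 4 pools with all libraries, and without scramble replicate 1 in pools 1, 3 and 4 and in pools 1 and 2. Luteal genes were called lower without scramble replicate 1 in pools 1, 2 and 4, and extracellular matrix genes and theca markers in pools 1, 3 and 4. With all libraries theca markers were called lower in pool 3, surface epithelium markers in pools 1 and 3 and cytoskeleton genes in pools 1 and 4. Lysosome, oxidative phosphorylation and ribosomal protein genes were called lower in all 4 pools with all libraries and in 0 without scramble replicate 1.

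**Figure D4:**
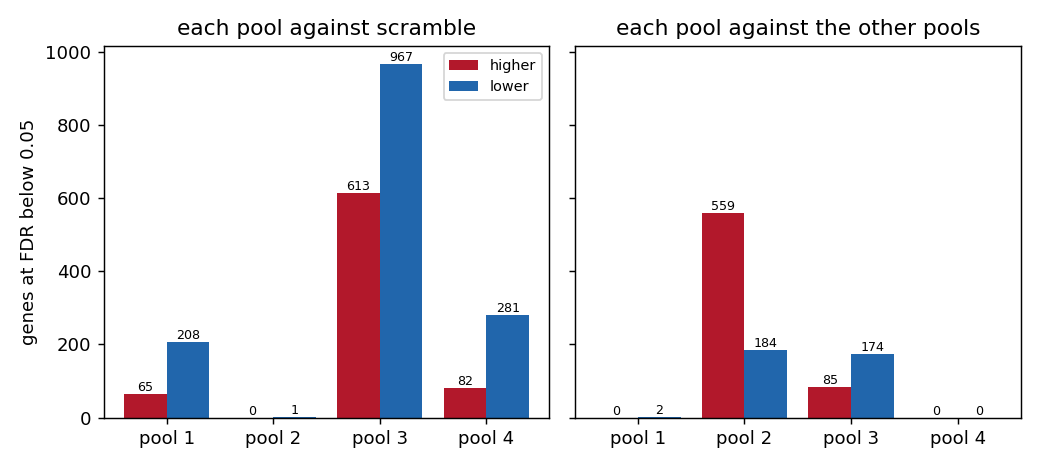
Genes at edgeR adjusted p below 0.05, all 11 libraries; bars give genes higher (red) and lower (blue) in each pool against scramble, left, and against the mean of the other 3 pools, right. Pool 2 has 1 call against scramble and 743 against the other pools.

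Genes that differed between pools were led by genes that were at the scramble level in pool 2 and low in the other pools. Ei24, a p53-induced gene, was at 141 ± 3.76 CPM in pool 2 and 137 ± 10.6 in scramble, but at 36.3 ± 2.07, 31.4 ± 0.107 and 34.9 ± 1.27 in pools 1, 3 and 4 (SD, n = 2 per pool and 3 for scramble). It was 2.04 ± 0.08 log2 (SE) higher in pool 2 than in the mean of the others (edgeR adjusted p = 3.2e-05). Cldnd1, a claudin-domain gene, was at 232 CPM in pool 2 and 50.7 to 67.9 in the other pools (log2 1.92 ± 0.08 SE, edgeR adjusted p = 5e-05). Dars, the cytosolic aspartyl-tRNA synthetase gene, was at 123 CPM in pool 2 and 43.1 to 49.9 in the others (1.39 ± 0.07, edgeR adjusted p = 7.5e-05). Tph1, Ap3m1, Mob3a and Nadk had the same form, with pool 2 higher by 1.20 to 1.74 log2. Of the named genes, Ei24, Cldnd1, Dars, Tph1, Ap3m1, Nadk, Fos, Snx30, Bcl7a and Ddit4 hold the 7-base word GTGCCAC in the 3′ UTR, the most enriched word among genes higher in pool 2. In mm10, Ei24 lies at 36779159 to 36797393 of chromosome 9, Cldnd1 at 58727910 to 58734251 of chromosome 16 and Dars at 128363707 to 128417368 of chromosome 1.

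Atg9b, an autophagy gene, went the other way. It was at 3.83 CPM in pool 2 and 3.85 in scramble, 9.95 and 10.0 in pools 1 and 4, and 21.5 in pool 3. Pool 3 was higher than the mean of the others by 1.57 ± 0.09 log2 (SE, edgeR adjusted p = 0.00103; 1.52 log2 and 0.063 without pool 3 replicate 1). Vash1, an inhibitor of angiogenesis, followed the same order at 7.15 CPM in pool 2, 15.5 and 16.6 in pools 1 and 4 and 32.1 in pool 3 (1.39 ± 0.11, edgeR adjusted p = 0.00683). The ATP receptor gene P2rx4 was at the scramble level in pool 3 (32.2 and 29.0 CPM) and at 13.3 to 14.7 in the other pools (1.21 ± 0.11, edgeR adjusted p = 0.00979). Vash1 and P2rx4 lost the call without either pool 3 library (lowest adjusted p = 0.20) and, at 0.053 to 0.061, without some libraries of other pools, where the differences stayed at 1.37 to 1.40 and 1.18 to 1.23 log2. The immediate early genes Fos and Egr1 were at 28.1 and 37.8 CPM in scramble. Pool 1 was below scramble for Fos (log2 −0.56, edgeR adjusted p = 0.0339). It was not called against scramble for Egr1 (−0.20, edgeR adjusted p = 0.465), where the other pools lay above scramble. Against the mean of the other pools, Fos and Egr1 were lower in pool 1, by −0.98 ± 0.09 and −1.17 ± 0.12 log2 (SE, edgeR adjusted p = 0.0447 each), at 19.1 against 31.5 to 51.0 CPM for Fos and 32.9 against 69.3 to 83.2 for Egr1. Both calls were lost without any 1 library other than scramble replicate 1 (edgeR adjusted p from 0.11), at differences of −0.92 to −1.04 log2 for Fos and −1.08 to −1.27 for Egr1.

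**Figure D5:**
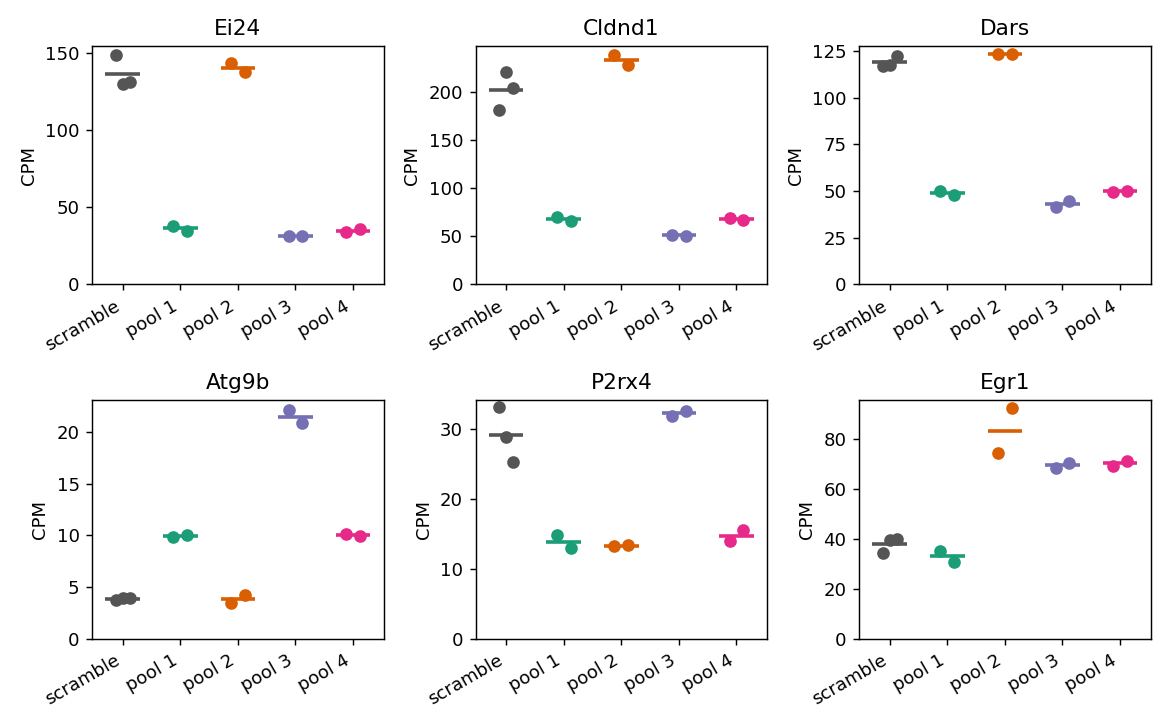
CPM of 6 genes named by the rule for differences between pools; points are libraries, lines are group means, and axes start at 0. Ei24 is at 141 CPM in pool 2 and at 31.4 to 36.3 in the other pools, and Atg9b is highest in pool 3 (21.5 CPM). P2rx4 is at 32.2 CPM in pool 3, and Egr1 is at 32.9 CPM in pool 1 and 37.8 in scramble.

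In all, 348 genes differed among the 4 pools (edgeR, 3 degrees of freedom; 6017 without scramble replicate 1 and 1072 with DESeq2). Against the mean of the other pools, 559 genes were higher and 184 lower in pool 2, and 85 were higher and 174 lower in pool 3. Fos and Egr1 were the 2 genes of pool 1. Pool 4 had 0 (edgeR, 192 at unadjusted p below 0.05, DESeq2 9, limma-voom 0). Without scramble replicate 1 the counts were 243, 6149, 5569 and 209 for pools 1 to 4. Without either library of pool 2 the count among pools was 6 or 16 and that of pool 2 was 111 or 113; without other pool libraries they were 59 to 125 and 346 to 385. The pool 3 count was 150 without scramble replicate 2 and at most 4 without any 1 pool library.

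Calls of pools 1, 3 and 4 overlapped. Pools 1 and 3 shared 261 genes, pools 1 and 4 shared 252 and pools 3 and 4 shared 350, each changed the same way with 0 in opposite directions. Independent lists of these sizes would share 17.0, 4.51 and 22.8. Simulated unchanged pools shared 0 in 50 runs, but they were centred on the mean of these same scramble libraries. That leaves out any chance shift of the scramble mean, so the 0 cannot tell how many shared calls come from shared controls. Part of the excess may come from the shared scramble libraries, and 3 libraries cannot be split into sets of 2. By the matched pool numbers, pools 1, 3 and 4 hold siRNA 7, which pool 2 lacks. Genes called in pools 1, 3 and 4 had a median absolute log2 change of 0.86, 0.77 and 0.85 there and, taken in the same direction, a median change of 0.11, 0.09 and 0.12 in pool 2. These genes were chosen on the first of these values, and the same scramble libraries enter both. Without scramble replicate 1, pools 1 and 3, 1 and 4, and 3 and 4 shared 3586, 3460 and 3908 calls in the same direction (999, 644 and 1076 for independent lists), with 22, 2 and 22 in opposite directions. With all libraries Akt1 was the 1 call of pool 2, so no other overlap with that pool could be seen. With scramble replicate 1 left out, pool 2 shared 334, 284 and 366 calls in the same direction with pools 1, 3 and 4 (92.5, 153 and 99.1 for independent lists) and 70, 156 and 58 in opposite directions. Akt1 was the 1 gene called the same way in all 4 pools. There were 251 such genes without scramble replicate 1, 66 higher and 185 lower, and DESeq2 on all libraries gave 555.

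The authors' deposited table of all pools against scramble lists 24490 genes, of which 404 were higher and 581 lower at an adjusted p below 0.05. In the authors' deposited table the log2 fold change of Akt1 was −2.63 with an adjusted p of 3.07e-80. Across 14144 genes, which are not independent replicates, the fold changes of the authors' deposited table correlated with those of edgeR with all libraries at r = 0.970. Of the 985 genes called in the authors' deposited table, 35 were called by edgeR without scramble replicate 1, among them Pik3ip1 and Lbh. The authors' deposited table gives no p for 2526 genes with a mean count above 0. Of these, 2512 were tested here, and scramble replicate 1 was the library farthest from the median for 99.0% of them.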

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

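Tests of transcript length, cell type, labels, Akt1 level and the gene lists by library, and the gene lists between pools and in single pools, were chosen only after the result was seen; the word search, the thinning and the splits of the libraries were set before their results were seen.

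Genes and lists that differed between pools lead what stood out. Among the 4 pools 348 genes differed, and against the mean of the other pools 2 differed in pool 1, 743 in pool 2 and 259 in pool 3. The F statistic over the 4 pools was 235 for Ei24, 181 for Cldnd1, 148 for Dars, 135 for Atg9b, 120 for Tph1, 108 for Ap3m1, 104 for Mob3a and 102 for Nadk. Differences from the mean of the other pools were 2.04 log2 for Ei24, 1.92 for Cldnd1 and 1.39 for Dars in pool 2, 1.57 for Atg9b, 1.39 for Vash1 and 1.21 for P2rx4 in pool 3, and −0.98 for Fos and −1.17 for Egr1 in pool 1.

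Among gene lists compared between pools, median log2 differences from the mean of the other pools in pool 1 were 0.54 for interferon-stimulated genes, 0.10 for cholesterol synthesis and −0.11 for cytoskeleton genes. In pool 2 they were 0.57 for cytoskeleton genes, 0.37 for granulosa cell markers, −0.43 for interferon-stimulated genes, −0.24 for cholesterol synthesis and −0.23 for mitosis. In pool 3 they were −0.30 for granulosa cell markers and 0.29 for mitosis. Pool 2 is part of the mean behind the values of pools 1 and 3. ERCC sequences took 0.788% of the counts of scramble replicate 1 and at most 0.558% of any other library. In pool 2 replicate 2, Ddit4 was at 32.6 CPM against 26.3 to 28.6 in the other 7 pool libraries (gap over range on the log2 scale 0.607; chance gives such a gap in about 1 of 20 values, and 39 were tested).

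Scramble replicate 1 stood apart from the other 10 libraries. The difference from the other scramble libraries fell with transcript length across genes (Spearman rho = −0.756, genes not being independent replicates), against −0.227 to 0.227 for the other libraries, so a bias of that library that follows length may account for much of it. RNA from another cell type cannot be told apart from it: surface epithelium and immune markers had medians of 0.80 and 0.48 log2 in that library against the other scramble libraries, and after the length trend is removed the highest median, of the surface epithelium list, was 0.22 (percentile 92.6 of random lists, and 92.7 for theca at 0.16). A pool library under a scramble label is excluded, since Akt1 was 6.66 times the highest pool library. Whether the bias arose in the RNA or in the library stays open, as no label records either.

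Genes that were higher in pool 2 than in the other pools may be off-target genes of siRNA 7, which pool 2 lacks. Of the 200 genes most higher in pool 2, 59.5% held the word GTGCCAC in the 3′ UTR against 12.1% in genes of like UTR length (BH adjusted p = 7.63e-53), first of 16384 words, and the word occurs once in the coding part of Akt1, in exon 10 at 112657111 to 112657117 of chromosome 12, as 13.9% of words do. The siRNA sequences are not given in the sources used here, so the match to siRNA 7 rests on pool numbers and on the word alone. Weaker knockdown in pool 2 is argued against, since the upper 95% bound of the difference of Akt1 from the other pools was 0.016 log2, and so is depth, since 674 of 743 genes remained called with every library thinned to 23851293 reads. Mob3a and Egr1, which were higher in pool 2 than in the mean of the other pools, lack the word, which is in 43.4% of all genes called higher in pool 2. Atg9b, Vash1 and P2rx4 lack it too, but they were not higher in pool 2, so this has no bearing on the explanation.

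Steroid and cholesterol synthesis lists were lower in the pools by camera with a preset correlation, which may follow from lower Akt1. Neither call held with an estimated correlation (adjusted p = 0.37 and 0.575). Fry, which compares a list with no other genes, passed steroidogenesis (fry adjusted p = 0.0099, and 0.0029 without scramble replicate 1). It did not pass cholesterol synthesis (0.0886 and 0.0635). Shifts of these lists relative to other genes are therefore not established. For steroidogenesis an off-target effect of 1 siRNA is argued against, as the median was at most −0.17 log2 in each of 4 pools against each of 3 scramble libraries, and so is a single odd scramble library, as the mean of the pools was at most −0.24 against each. For cholesterol synthesis neither can be told apart from an Akt1 effect: with all libraries the list passed in pool 2 alone of single pools, the highest median of the 12 pairs was 0.021, and against scramble replicate 1 the list lay at percentile 19.9 of random lists. An effect of the scramble siRNA itself cannot be separated, since no untreated cells are among the groups. Nor can off-target effects of 2 or more siRNAs, since each pool lacks only 1 and so holds at least 1 of any 2. The 12 pairs reuse the same libraries and are not independent checks.

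For the number of lists called chance cannot be excluded: 10 of 100 splits of the 11 libraries into 3 and 8 called as many (real 13, highest other 15). These splits ignore the pools, among which 348 genes differed, so their counts may hold differences between pools as well as chance: both pool 2 libraries with pool 4 replicate 2, for example, gave 13. For single genes 3 of 100 splits called as many (real 1, highest other 3), but the 1 gene is Akt1, the siRNA target, so the count says nothing of other genes.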

How the results depend on the processing

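The omission of pools and libraries, the tools and the filters were chosen before; the alternatives for gene lists between pools and in single pools were chosen after seeing the data, as was the reapplied naming of genes without scramble replicate 1. Of the values for single genes and lists under the alternatives, 1273 kept their direction and their side of the threshold, 135 newly passed it, 143 no longer passed and 23 changed direction, for lists the direction of the camera test. Of the main counts and Akt1 levels, 207 stayed within 1.5 times or on the same side, 32 were higher by more or newly passed, and 77 were lower by more or no longer passed. Where not said otherwise, the cause was not tested. List medians in this section are over log2 CPM differences, not edgeR log2 fold changes. With every library thinned to 23851293 reads, 717 genes differed between pool 2 and the other pools, against 743 before, so depth did not set that count. Where the omission of a library leaves a pool with 1 sample, that sample is assumed to vary like the other groups.

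For all pools against scramble, where 1 gene was called, RLE scaling gave 2, no low-count filter 2, DESeq2 1147 and the 5-group fit 901. The omission of pool 2 gave 1390 and of pool 3 gave 7. Limma-voom with the group (a pool or scramble) as a random effect gave 1121, at an estimated correlation of −0.14 within a group. Scramble, with replicate 1 standing apart, is 1 of these groups. The value therefore does not measure how alike the libraries of a pool are. A value below 0 adds no differences between pools to the error, so the 1121 calls do not allow for them. DESeq2 gave 788 in pool 1, 28 in pool 2, 872 in pool 4, 1072 between pools, 9, 1275, 854 and 9 for pools 1 to 4 against the others, and 555 the same way in all 4. No low-count filter gave 158 for pool 3 against the others. With a pool and scramble libraries alone, which leaves fewer samples, 0 genes were called in each pool in edgeR, and the Akt1 levels were −2.94, −3.07, −2.56 and −3.00 (edgeR adjusted p = 0.278, 0.205, 0.085 and 0.276). Of the gene lists 0 were called with an estimated correlation and 6 with fry.

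The replicate numbers are shared between groups, but same-numbered libraries did not deviate together (r from −0.046 to 0.073, 0 of 20 pairs above 0.1). With the replicate number as a block, 1649 genes were called for all pools, 96 in pool 1, 151 in pool 4, 146 between pools, 0 in pool 1 and 51 in pool 3 against the other pools. Only scramble has a replicate 3, so the block also takes that library out of the comparison; its omission alone gave 2336, 219, 327, 335, 0 and 254. The direction of the camera test turned for luteal genes, immune markers and TGF-beta genes, whose medians of 0.14, 0.24 and 0.076 with the block were also those without scramble replicate 3.

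Without 1 library at a time, counts ran from 1 to 2336 for all pools, 9 to 4044 in pool 1, 1 to 618 in pool 2, 210 to 6864 in pool 3 and 17 to 4364 in pool 4. They ran from 6 to 6017 between pools, 0 to 243, 111 to 6149, 0 to 5569 and 0 to 209 for pools 1 to 4 against the others, 1 to 251 the same way in all 4 pools and 10 to 13 for lists. Akt1 ran from −2.95 to −2.76 over all pools, and from −3.01 to −2.82, −3.14 to −2.96, −2.63 to −2.45 and −3.08 to −2.88 in pools 1 to 4. The log2 change of Mlf1 ran from −0.014 to 0.61. Where the direction of the camera test turned, which need not turn the sign of the median, median log2 CPM differences ran from −0.055 to 0.35 for the AKT list, −0.045 to 0.029 for NF-kB, −0.13 to 0.076 for TGF-beta, −0.59 to 0.022 for ribosomal proteins, −0.12 to 0.17 for extracellular matrix, 0.14 to 0.82 for immune markers and −0.22 to 0.24 for luteal genes. Without scramble replicate 3, luteal genes were at 0.14 and immune markers at 0.24; without pool 3 replicate 1, TGF-beta was at 0.025; without scramble replicate 2 it was at −0.011. Without scramble replicate 1, NF-kB was at −0.042 and ribosomal proteins in pools 1 to 4 at 0.039, 0.036, −0.0083 and 0.0091. Without pool 3, immune markers were at 0.22, NF-kB at −0.032 and TGF-beta at 0.036, and with CPM above 1 in all libraries luteal genes were at 0.095.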

Other observations

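The comparison of gene lists between pools, with its alternatives, was chosen after seeing the data, while the lists themselves were fixed before.

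Interferon-stimulated genes had the smallest adjusted p of the lists compared between pools. Their median was 0.54 log2 above the mean of the other pools in pool 1 (camera adjusted p = 2.34e-33, adjusted p = 0.152 with an estimated correlation) and −0.43 in pool 2 (0.000113, adjusted p = 0.542 with an estimated correlation). Granulosa cell markers were higher in pool 2, with a median of 0.37 and 4 members called higher by edgeR (camera adjusted p = 0.000106, adjusted p = 0.0686 with an estimated correlation), and lower in pool 3, with a median of −0.30 and 2 members called lower (2.76e-05, adjusted p = 0.0515 with an estimated correlation). Cytoskeleton genes and targets of the transcription factor SRF were higher in pool 2, with a median of 0.57 and 10 members called higher and 1 lower (camera adjusted p = 0.000106, adjusted p = 0.509 with an estimated correlation). They were lower in pool 1 (median −0.11, camera adjusted p = 2.02e-09, adjusted p = 0.279 with an estimated correlation), where pool 2 is part of the mean. Against scramble replicates 2 and 3 their medians were −0.38, −0.36 and −0.32 in pools 1, 3 and 4 and 0.07 in pool 2.

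Mitosis genes were lower in pool 2 (median −0.23, camera adjusted p = 0.000158, adjusted p = 0.136 with an estimated correlation) and higher in pool 3 (0.29; 2.62e-07, adjusted p = 0.0515 with an estimated correlation). Cholesterol synthesis genes were lower in pool 2 (median −0.24, camera adjusted p = 0.000178, adjusted p = 0.249 with an estimated correlation). They were higher in pool 1 (0.10, camera adjusted p = 7.91e-05, adjusted p = 0.245 with an estimated correlation), where pool 2 is part of the mean. Against scramble replicates 2 and 3 their medians were −0.17, −0.085 and −0.17 in pools 1, 3 and 4 and −0.38 in pool 2. Of 108 tests of a list in a pool against the other pools, 20 passed with camera, 19 without scramble replicate 1, and 0 with an estimated correlation. The 10 described above had a camera adjusted p below 0.001. Other marker lists that passed were theca and stroma, lower in pool 3 (median −0.18, camera adjusted p = 0.00116) and higher in pool 2 (0.18, 0.0446). Surface epithelium markers were lower in pool 3 (−0.19, camera adjusted p = 0.0344) and immune markers higher (0.51, 0.00905). Endothelial markers were higher in pool 1 (0.17, camera adjusted p = 0.00731).

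The word GTGCCAC was also the most enriched word among the 200 genes most lower in pools 1, 3 and 4 against the other pools, at 38.0%, 42.5% and 44.5%; pool 2 is part of the mean in each of these, so they are not independent of it. Against scramble, without scramble replicate 1, 43.1%, 52.1% and 44.6% of genes with the word were called lower in pools 1, 3 and 4, against 14.8%, 24.3% and 15.6% of genes without it, and 2.54% against 2.88% in pool 2. The median log2 changes of genes with the word were −0.14, 0.0031, −0.22 and −0.15 in pools 1, 2, 3 and 4, against −0.00017, 0.0057, 0.0056 and 0.0011 in genes of like 3′ UTR length without it. The word was found in the same libraries, so these values are no independent test. In the authors' deposited table the word was in 18.2% of genes called lower and 6.40% of those called higher, against 10.9% of all genes searched (odds ratio 1.88 for genes called lower, Fisher's exact test p = 1.64e-07, across genes). That comparison is no independent test either, since the authors' calls are of the same series in which the word was found. It was also not matched on 3′ UTR length.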
